A study of Caenorhabditis elegans with 6 samples.

How the data were processed

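The series held 4 Hi-C libraries and a ChIP-seq peak list from mixed-stage embryos of the nematode Caenorhabditis elegans. Hi-C counts how often pairs of genomic regions are ligated to each other after digestion of the chromatin, here with DpnII per the labels. Rex sites are the X-chromosome elements that recruit the dosage compensation complex, the complex that lowers X expression in hermaphrodites. Each Hi-C strain had 1 library: a strain that lacks 8 rex sites on X, and 3 strains that lack the same sites and carry 1 inserted site, rex-32, rex-40 or rex-23. By genotype order in the labels, each insertion lies between the deleted rex-33 and rex-14. The position itself is not given in the sources used here.

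For each Hi-C library the authors deposited a matrix of balanced contact signal in bins of 50 kb on build ce11, in which each of the 1984 bins with contacts summed to 504.0 and the diagonal and its first neighbour were 0. Because the values were balanced, the read depth is unknown and no interval that needs it is given. The authors also deposited an insulation score on a log2 scale for 1938 bins per library. Recomputing it as the log2 of the mean contact in a square of 10 by 10 bins (500 kb on each side) over its genome-wide mean gave the deposited score in 1938 of 1938 bins of each library, within 1e-06 after a constant per library was removed. A low score marks a bin across which few contacts pass. The third deposited table held a z-score for each contact within a chromosome against a loess expectation for its distance, made with cworld::dekker matrix2loess.pl version 0.41.1 per the file headers. The aligner and the balancing tool for Hi-C are not given in the sources used here. The headers of the z-score tables date the deletion library to 2016, the rex-32 and rex-40 libraries to 2018 and the rex-23 library to 2019, so the recorded year was shared by the rex-32 and rex-40 libraries and cannot be told apart from strain in the other comparisons.

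The ChIP-seq peak list is filed with the IgG control sample of wild-type embryos, and that it holds SDC-3 peaks called against that control was read from its name. SDC-3 is a subunit of the dosage compensation complex. Bowtie 0.12.7 and MACS 1.4 are named in the submitters' processing notes. Each peak carried a score deposited by the authors, used only to rank and filter peaks within the list. The score 3100 was shared by many peaks, as a ceiling would be, so ties were ordered by peak width. It is called the ceiling here although scores on X reached 3208.54. The build of the list was read only from its name, WS190, and no annotation of that build was used. Peaks were therefore not joined to Hi-C bins or to genes. Peak starts are given counting from 1.

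The insertion bin was to be located, for each insertion strain, as the X bin with the lowest mean change of score in the other 2 insertion strains. The 3 locations lay up to 5.3 Mb apart, beyond the 150 kb allowed before the data were examined, so the main value for each strain is its own lowest X bin, chosen in the same data. A second locator was added after seeing the data. Reads from an inserted copy align to the native place of that sequence, so the pair of bins on 1 chromosome, over 1 Mb apart, with the highest excess of contact over the mean of the other 3 libraries was taken in each insertion strain. The excess was divided by the square root of the mean plus 0.2. This locator does not read the insulation score, and its bin is used for the contacts across the bin, the local depth of the dip, the differences between strains and the far partners.

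Changes of score are the insertion strain minus the deletion strain. Contacts across the bin are the mean change of log2 observed over expected contact between the 10 bins on each side, the expectation being the mean of the same chromosome and distance. Local depth is the mean score of bins 4 to 10 away on both sides minus the lowest score of the bin and its neighbours. A minimum of the score was the lowest value within 5 bins on each side, at least 0.3 below the mean of the flanking maxima within 10 bins. With 1 library per strain there is no replicate check on any difference and no p-value. Values are set instead, except where stated, against the same quantity over autosomal bins, as a description of these libraries. The share of peaks on X has a 95% Wilson interval, which covers counting error only.

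Named regions followed a rule fixed before the data were examined: the insertion bin, the 3 lowest and 3 highest X bins per strain (bins within 3 of one already taken were passed over), the lowest and highest autosomal bin, the 5 far partners with the highest mean gain, up to 10 deepest X minima present in all 4 libraries, and the 10 highest peaks on X and 5 on autosomes. Genes in Hi-C bins were taken from the RefSeq annotation of WBcel235, the same assembly as ce11.

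The functions were tested on simulated data made from the deletion library's own matrix with noise. In a run over 2008 bins, a planted change of -0.3 at 9 sites came back as a mean of -0.28, a change of -0.2 at 9 sites as -0.18, and a change of -0.1 at 9 sites as -0.084. Where none was planted, at 10 sites, the mean was 0.0092 with an SD of 0.0067. The noise was drawn independently for each contact. In the real comparisons the SD over autosomal bins was 0.044, 0.032 and 0.059 in the rex-32, rex-40 and rex-23 strains. The run therefore checks the functions and does not show how small a real change can be detected. Alternatives covered the size of the square, the centring and scaling of scores, the control, the locator, the z-scores, the flanks, the depth of minima and the peak threshold. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.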

Results

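Chromosome contacts were measured by Hi-C in embryos of 4 strains, 1 library each: a strain lacking 8 rex sites on X, called the deletion strain, and 3 strains in which rex-32, rex-40 or rex-23 had been inserted into that X. SDC-3 binding in wild-type embryos was given as a list of 1594 peaks. Of 2008 bins of 50 kb, 1984 had contacts in each library, and 340 X bins and 1598 autosomal bins had an insulation score. Across bins, which are not independent replicates, the scores of the deletion strain correlated with those of the rex-32, rex-40 and rex-23 strains at Pearson's r of 0.982, 0.991 and 0.971. Contacts between chromosomes made up 28.5% of the signal in the deletion strain, 23.4% in the rex-32 strain and 26.1% in the rex-40 strain, with the rex-23 strain between the deletion and rex-40 strains. Of pairs of bins on different chromosomes, 0.083% had a contact of 0 in the rex-32 strain. In the deletion, rex-40 and rex-23 strains the share was 0.020%, 0.022% and 0.018%. The cause of this difference was not tested.

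The position of the insertion was read from contacts. In every insertion strain the bin X:7,800,001-7,850,000 (ce11) gained a single far contact that was much lower in the other strains. In the rex-32 strain the partner was X:2,950,001-3,000,000, with a contact of 4.85 against 0.433 in the deletion strain. In the rex-40 strain it was X:800,001-850,000, at 2.59 against 0.293. In the rex-23 strain it was X:4,200,001-4,250,000, at 3.21 against 0.668. Each was the most outlying of 293737 pairs of bins within chromosomes in its library, with an excess of 6.13, 3.37 and 2.32 where the next pair reached 1.26, 0.768 and 0.584. That bin overlaps 16 annotated genes, of which 8 code for protein. Among them are sek-1 (X:7,816,734-7,821,036), a MAP kinase kinase of the p38 pathway, eef-1A.2 (X:7,823,654-7,825,769), a translation elongation factor, sul-3 (X:7,827,085-7,834,217), a sulfatase, nlp-101 (X:7,838,882-7,839,381), idpp-11 (X:7,842,541-7,845,557), and cca-1 (X:7,847,678-7,875,954), a calcium channel subunit that runs into the next bin.

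**Figure D1:**
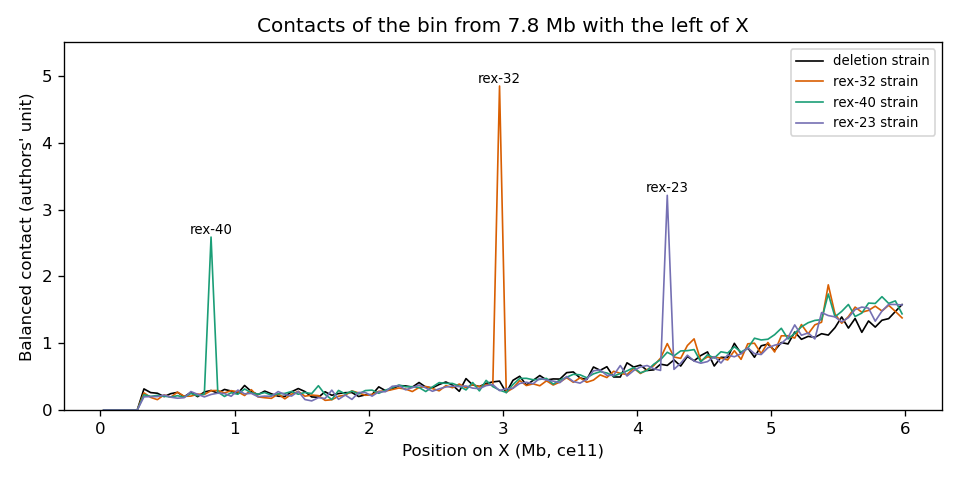
Balanced contact (authors' unit) of the bin X:7,800,001-7,850,000 with bins of the left 6 Mb of X, 1 line per strain. The rex-40, rex-32 and rex-23 strains each show a single spike, at 0.8, 2.95 and 4.2 Mb.

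The first comparison asked whether an inserted rex site lowers the insulation score where it lies. In the rex-32 strain the score at X:7.8 Mb was -0.41, against -0.10 in the deletion strain, a change of -0.30. Taken relative to each library's own genome-wide mean, the contact across the bin was 0.81 times that of the deletion strain. None of 1598 autosomal bins fell as far, and the change was the lowest on X. In the rex-40 strain the score at the same bin was -0.15, a change of -0.048, with 4.13% of autosomal bins as low and a rank of 54 among 340 X bins. In the rex-23 strain it was -0.19, a change of -0.088, with 6.01% of autosomal bins as low and a rank of 5 on X. With a 250 kb square the changes of the rex-40 and rex-23 strains were -0.020 and -0.055, with a 1 Mb square they were -0.090 and -0.13, and with scores centred on the median of X the rex-40 change was -0.029. The SD of the change over autosomal bins was 0.044, 0.032 and 0.059 in the rex-32, rex-40 and rex-23 strains. By the rule set before the data were examined, which fell back on each strain's own lowest X bin, the values were -0.30 at 7.8 Mb for rex-32, -0.078 at 2.05 Mb for rex-40 and -0.12 at 2.5 Mb for rex-23. These bins were chosen in the same data and were not stable: the rex-40 bin was at 15.95 Mb with a 250 kb square, at 7.8 Mb with a 1 Mb square and at 0.5 Mb with the other 2 insertion strains as the control, and the rex-23 bin at 4.25 Mb with a 250 kb square and at 7.8 Mb with a 1 Mb square. None of these differences has a replicate check.

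**Figure D2:**
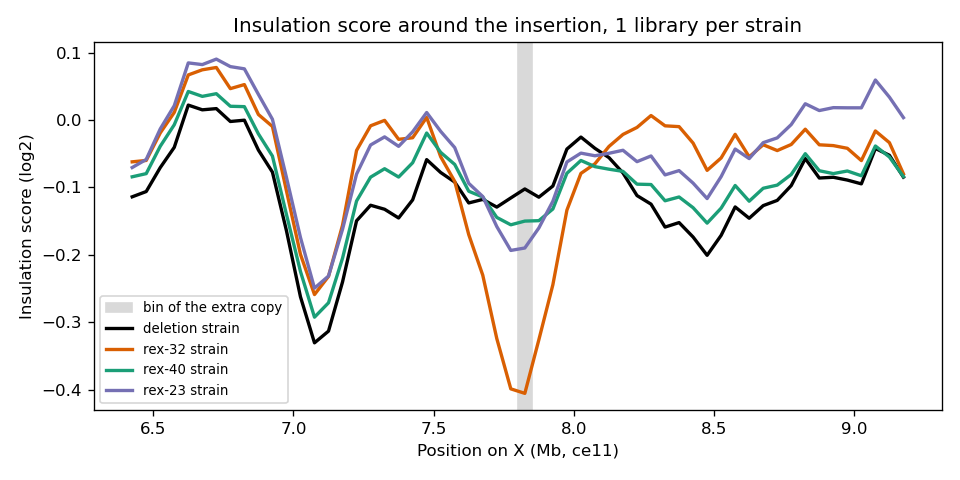
Insulation score (log2) against position on X (Mb, ce11) around the insertion, 1 line per strain, the grey band marking the bin from 7.8 Mb. The rex-32 strain reaches -0.41 in the band, the rex-23 strain -0.19, the rex-40 strain -0.15 and the deletion strain -0.10.

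Within a library, the dip at 7.8 Mb can be measured against its own flanks without the deletion strain. Its local depth was 0.36 in the rex-32 strain, 0.15 in the rex-23 strain, 0.081 in the rex-40 strain and 0.020 in the deletion strain. In the deletion strain 50.9% of 1498 autosomal bins were as deep, in the rex-40 strain 29.0%, in the rex-23 strain 12.6% and in the rex-32 strain 3.27%. Set against the deletion strain, the dip deepened by 0.34, 0.13 and 0.061 in the rex-32, rex-23 and rex-40 strains. That change ranked 1 among 320 X bins in each insertion strain, while 0, 4 and 21 of the 1498 autosomal bins changed as much. The same deletion library was subtracted in each case, so these ranks are not independent of each other. With a 250 kb square the rex-40 value was 0.0087, matched by 31.8% of autosomal bins.

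Contacts between the 500 kb on the left and the 500 kb on the right of the bin changed by -0.31 (log2) in the rex-32 strain, -0.11 in the rex-23 strain and -0.032 in the rex-40 strain. None of 1524 autosomal bins was as low as the rex-32 value, 1.25% were as low as the rex-23 value and 9.51% as low as the rex-40 value. Among 331 X bins these values ranked 1, 5 and 35. Contacts inside the left 500 kb changed by 0.11, 0.088 and 0.070 in the rex-32, rex-23 and rex-40 strains, and inside the right 500 kb by 0.11, 0.034 and 0.034. These changes inside each side were not set against autosomal bins, and all used the same deletion library. With squares of 5 bins the rex-23 value across the bin was -0.060, or -0.98 SD of autosomal bins where it had been -2.27 SD, and the rex-40 value was 0.015, the other sign. With squares of 20 bins the rex-23 value was -0.13 (-3.31 SD) and the rex-40 value -0.092 (-4.14 SD).

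The second comparison asked whether the 3 sites differ, without use of the deletion strain. At X:7.8 Mb the score of the rex-32 strain minus that of the rex-40 strain was -0.26, and 0 of 1598 autosomal bins differed as much in either direction. The rex-32 strain minus the rex-23 strain was -0.22, with 1.13% of autosomal bins as far from 0. The rex-40 strain minus the rex-23 strain was 0.040, which 35.3% of autosomal bins matched or passed, and 0.076 with scores centred on the median of X. In local depth, the rex-40 strain minus the rex-23 strain was -0.069, as far from 0 as 5.47% of autosomal bins.

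Of the X bins that moved most, X:7.30 Mb was among the highest in the rex-32 and rex-23 strains, and X:2.50 Mb among the lowest in the rex-40 and rex-23 strains. In the rex-32 strain the next lowest X bins were X:11.80 Mb, at -0.19, which holds rsd-3, mtcl-1 and taf-7.1, and X:1.95 Mb, at -0.14, which holds meg-3, a P granule component. Its highest were X:8.30 Mb, at 0.15, with the innexin gene inx-5, X:7.30 Mb, at 0.13, with sng-1, and X:8.50 Mb, at 0.11, with the neuropeptide gene flp-5. The bins at 7.30 and 8.30 Mb lie on the left and right of the insertion, and their changes were 0.060 and 0.039 in the rex-40 strain and 0.11 and 0.077 in the rex-23 strain. In the rex-40 strain the lowest bins were X:2.05 Mb (lsy-2), at -0.078, X:2.30 Mb (hum-6), also at -0.078, and X:2.50 Mb (syg-1), at -0.074, and the highest were X:7.35 Mb, at 0.061, X:8.45 Mb (dpy-6, mec-10), at 0.048, and X:7.10 Mb, at 0.042. In the rex-23 strain the lowest were X:2.50 Mb (-0.12), the insertion bin (-0.088) and X:3.40 Mb (-0.074), which holds the vitellogenin gene vit-5, and the highest were X:11.75 Mb, at 0.14, which holds ttx-3, a homeodomain gene of interneurons, X:9 Mb, at 0.11, and X:7.30 Mb, at 0.11. The bins at X:1.95, 11.75 and 11.80 Mb lie at or next to minima of the score found in all libraries. The minima at X:2.00 and 11.75 Mb were 0.81 and 0.70 deep in the rex-32 strain and 0.67 and 0.57 in the deletion strain. At X:11.75 Mb the depth was 0.42 in the rex-23 strain. Whether these changes belong to the bins or to the library was not tested.

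**Figure D3:**
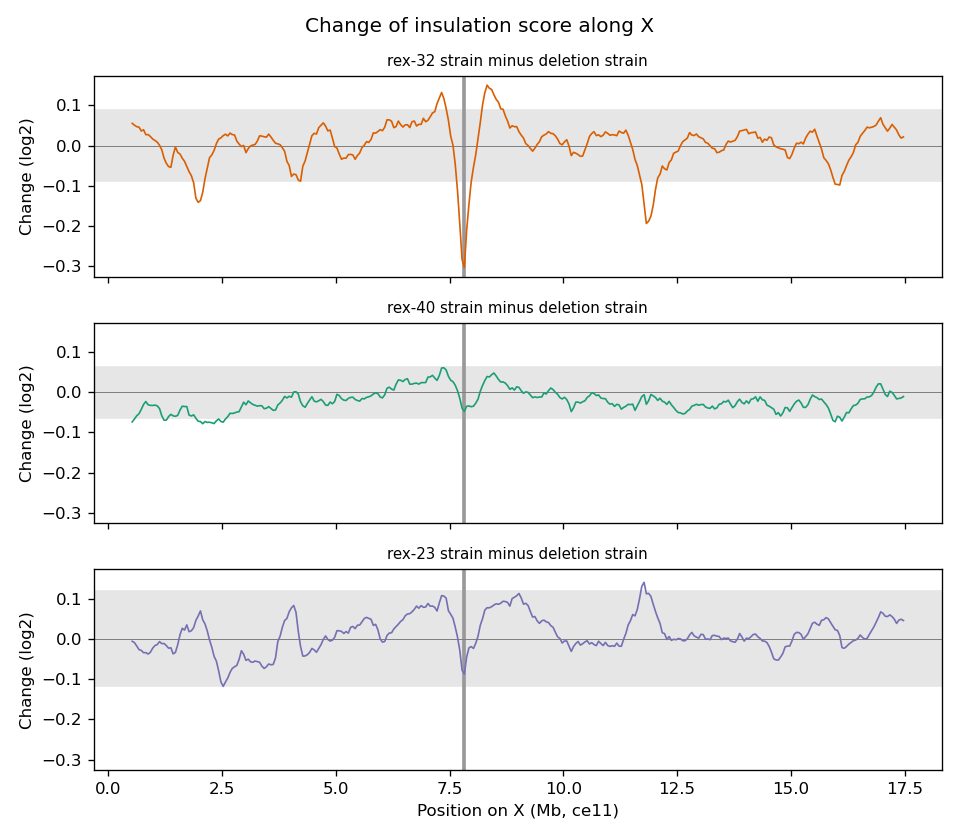
Change of insulation score (log2, insertion strain minus deletion strain) against position on X (Mb, ce11), 1 panel per strain, with the insertion bin as a vertical band and 2 SD over autosomal bins on each side of 0 as a grey area. The rex-32 strain falls to -0.30 in the band, and the rex-40 and rex-23 strains stay inside the grey area there.

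On autosomes the lowest bins were I:1.4 Mb in the rex-32 strain (-0.21), V:18.90 Mb in the rex-40 strain (-0.20) and III:0.30 Mb in the rex-23 strain (-0.25). The highest was IV:2.30 Mb in the rex-32 and rex-40 strains, at 0.19 in both, a bin with the ETS factor gene lin-1 and the proton pump genes vha-11 and vha-3. In the rex-23 strain it was V:0.25 Mb, at 0.24. Of these 6 values, 5 lay next to a bin that held no contacts in some libraries and did in others.

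Along X as a whole, the score had an SD of 0.19 in the deletion strain, 0.21 in the rex-32 strain, 0.18 in the rex-40 strain and 0.18 in the rex-23 strain. Single autosomes ranged from 0.21 to 0.26 in the deletion strain and from 0.22 to 0.28 in the rex-32 strain. Minima at least 0.3 deep numbered 5 on X in the deletion, rex-40 and rex-23 strains and 7 in the rex-32 strain, and 4 lay within 1 bin in all 4 libraries. On autosomes I to V such minima numbered 3, 4, 5, 3 and 6 in the deletion strain and 5, 7, 6, 5 and 6 in the rex-32 strain. The higher count of the rex-32 library was therefore not particular to X. At a depth of 0.15, 10 X minima were present in all 4 libraries. The deepest in the deletion strain were at X:2.00 Mb (0.67), X:11.75 Mb (0.57), X:4.05 Mb (0.46), X:5.00 Mb (0.41) and X:7.05 Mb (0.31). The others, at X:3.00, 1.30, 14.90, 14.35 and 10.30 Mb, were between 0.29 and 0.17 deep. The minimum at X:7.05 Mb was 0.30 deep in each insertion strain. A minimum lay at 7.8 Mb in the rex-32 strain, 0.41 deep, at 7.75 Mb in the rex-40 and rex-23 strains, 0.12 and 0.18 deep, and at 7.70 Mb in the deletion strain, 0.087 deep.

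Contacts of X at 0.1 to 1 Mb were close to those of autosomes, with log2 ratios of 0.023 in the deletion strain, 0.031 in the rex-32 strain, -0.0033 in the rex-40 strain and 0.040 in the rex-23 strain. At 1 to 5 Mb the ratios were -0.038, -0.057, -0.017 and -0.062. In each library these means were smaller than the SD over single autosomes, each set against the others, which was 0.085 and 0.089 in the deletion strain. With medians the same held except in the rex-23 strain at 0.1 to 1 Mb, where X was at 0.046, above all 5 autosomes (highest 0.032) and 2.53 SD from 0.

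Far partners of the insertion bin were compared to ask whether the inserted sites gained the same contacts. The 5 X bins with the highest mean gain were X:2.95, 4.2, 0.8, 1.90 and 11.95 Mb. The first 3 were the partners named above, with gains of 2.28 at X:2.95 Mb in the rex-32 strain, 1.31 at X:4.2 Mb in the rex-23 strain and 1.94 at X:0.8 Mb in the rex-40 strain. X:4.2 Mb also gained 0.47 in the rex-32 strain and 0.29 in the rex-40 strain. X:2.95 Mb changed by -0.077 in the rex-40 strain and 0.0020 in the rex-23 strain. X:0.8 Mb changed by 0.014 in the rex-32 strain and -0.092 in the rex-23 strain. The mean gain at X:2.95 and 0.8 Mb thus came from a single strain each. X:1.90 Mb gained 0.33, 0.32 and 0.73, and X:11.95 Mb gained 0.52, 0.37 and 0.29, in the rex-32, rex-40 and rex-23 strains. These bins were picked for their mean gain over the 3 strains against the same deletion library. Gains in all 3 strains are therefore partly built in and do not show common partners. Of the 10 top partners, 0 were shared by the 3 strains, where autosomal bins shared 1.47 on average, a number that includes what the common deletion library adds. Of the 20 top partners 4 were shared, against 3.66. The first partner of each strain was the far contact that located the insertion. That contact differed by strain and was not left out of these counts.

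SDC-3 peaks in wild-type embryos lay almost entirely on X: 1525 of 1594 peaks, 95.7% (95% Wilson interval 94.6 to 96.6). Over the span between first and last peak, X held 87.6 peaks per Mb, and autosomes from 0.845 (II) to 1.27 (V). Peaks on X had a median score of 128.5, those on autosomes 77.3. The highest scores on X (WS190) were 3208.54 at X:15,654,689-15,655,945 and 3119.12 at X:11,471,655-11,475,107. Next, at the ceiling of 3100 and taken by width, came X:5,422,399-5,436,729, X:14,809,211-14,820,340, X:4,207,693-4,217,341, X:16,203,045-16,212,597, X:801,992-811,207, X:8,034,827-8,042,079, X:12,362,056-12,368,175 and X:13,699,258-13,705,366. As 3208.54 and 3119.12 lie above 3100, that value is not a strict upper limit. Whether those peaks bind more SDC-3 than the peaks at 3100 cannot be read from the score. At or above the ceiling lay 73 X peaks (4.79%, interval 3.82 to 5.98), of which 17 fell between 1 and 2 Mb, and 7 autosomal peaks (10.1%, interval 5.00 to 19.5). The 5 autosomal peaks named by the rule were all on V, at V:9,697,944-9,700,266, V:3,043,413-3,045,442, V:3,040,587-3,042,055, V:9,696,455-9,697,873 and V:7,646,759-7,647,800.

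**Figure D4:**
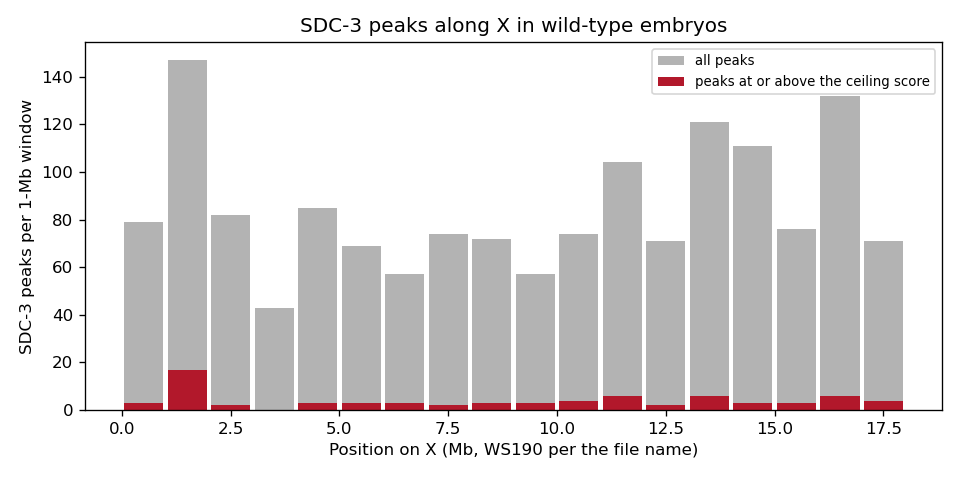
SDC-3 peaks in wild-type embryos per window of 1 Mb along X (WS190 per the file name), with all peaks in grey and those at or above the ceiling score in red. The window from 1 Mb holds 147 peaks, 17 of them at the ceiling, and the window from 3 Mb holds 43 with 0.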

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

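The test of the contrast of the rex-32 library was set before its result was seen, and the other tests in this part after. The bin X:7,800,001-7,850,000 had a far contact of 4.85 in the rex-32 strain, 2.59 in the rex-40 strain and 3.21 in the rex-23 strain, above the 0.433, 0.293 and 0.668 of the deletion strain at the same pairs, a signal outside the insulation score. At X:11.75 Mb the score changed by -0.14 in the rex-32 strain and by 0.14 in the rex-23 strain, each over 2 SD of autosomal bins and in opposite directions. That difference was not tested, as each strain had 1 library. The bin is a minimum in all 4 libraries, 0.70 deep in the rex-32 strain, 0.42 in the rex-23 strain and 0.57 in the deletion strain. The minima at X:2.00 Mb (0.81, 0.53 and 0.67) and X:4.05 Mb (0.55, 0.35 and 0.46) stood in the same order.

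The dip at 7.8 Mb was shallow in the rex-40 and rex-23 strains, so drift between libraries was weighed. In the rex-23 strain at most 4.76% of autosomal bins, over 3 settings, had a change of local depth as large. That is just under a 5% limit set after the result was seen, and 6.01% of autosomal bins had a change of score as low. The test therefore cannot exclude slow drift there. In the rex-40 strain the highest was 31.8%, from the 250 kb square, against 21 of 1498 bins with the score as deposited, so drift cannot be told apart from a weak dip. Rescaling by balancing after reads of the extra copy was also weighed. For this, those contacts were set to the level of the deletion strain and the matrix was balanced again. The change then shrank by at most 2.09% in the rex-40 strain and 0.947% in the rex-23 strain, over 4 settings. The score at a bin leaves out the contacts of that bin itself. A small shrinkage was therefore largely fixed in advance, and no conclusion is drawn from it. An effect of inserted DNA as such stays open, since 0 of the 4 libraries carried an insert without a rex site, and so does a property of the inserted rex sites.

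The deeper dip of the rex-32 strain was weighed against a library of higher contrast. The 10 other shared X minima were deeper in that library by a median ratio of 1.20 over the rex-40 strain and 1.28 over the rex-23 strain, and by at most 1.30 and 1.65. In the same measure the minimum at the insertion was 3.55 and 2.33 times as deep, which argues against contrast as the whole cause. In the rex-32 strain the excess of the extra-copy contact over the deletion strain was 1.73 times that of the rex-23 strain. It was 1.92 times that of the rex-40 strain, and both ratios were below those of the dips, 2.33 and 3.55. More inserted sequence in the rex-32 strain may contribute and cannot be told apart from a difference between the sites. Whether that contact measures the amount of inserted sequence was not tested. The recorded year of processing was 2018 for both the rex-32 and rex-40 libraries, whose scores differed by -0.26, so it does not separate those 2; the year of the rex-23 library and the identity of the site stay open as untested.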

How the results depend on the processing

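No paired analysis was possible because each strain had 1 library. Of 146 alternative settings, 25 changed the sign of a value. In 4 of them the main value lay at least 1 spread from 0, and these are called reversed, a limit set after seeing the data. The other 21 were contact ratios of X to autosomes near 0, 19 with an autosome in place of X and 2 with the median in the rex-40 strain (0.011 at both distances). By the limits used, 101 settings left the value the same and 41 moved it. The 21 settings with a change of sign near 0 are spread over both of these groups. These counts do not measure how stable the results are. They include settings with an autosome in place of X, which do not reprocess the X value. Some lowest bins were called the same in value although their place on X moved. The rex-32 change at 7.8 Mb was counted under both locators. The choice of the 7.8 Mb bin, and the settings for its change of score and of dip depth, were added after seeing the data. Unless stated, the cause was not tested. With the bin located in the other 2 strains, the rex-32 change was 0.025, at 2.5 Mb. With the other 2 insertion strains as the control, which also carry an insertion, the change at 7.8 Mb was -0.24 (rex-32), 0.15 (rex-40) and 0.088 (rex-23). There the rex-40 change was -0.090 with a 1 Mb square, -0.020 with a 250 kb square and -0.029 with centring on the median of X, and the rex-23 change -0.055 with a 250 kb square. Across the bin, rex-40 gave 0.015 with 5 bins and -0.092 with 20, and rex-32 gave -0.84 in z-score units. Local depth with flanks 3 to 6 bins away was 0.044 (deletion) and 0.30 (rex-32), and with the 250 kb square 0.088 (deletion), 0.44 (rex-32) and 0.18 (rex-23). Its change was 0.25 (rex-32) and 0.035 (rex-40) with the nearer flanks and 0.0087 (rex-40) with the 250 kb square. Without chromosome ends, the SD on X was 0.17, 0.18, 0.15 and 0.15 (deletion, rex-32, rex-40, rex-23). Minima on X numbered 12, 13, 11 and 12 at a depth of 0.15 and 2, 3, 2 and 1 at 0.5, by construction. Single autosomes in place of X gave, at 0.1 to 1 Mb, 0.11 (III) and -0.090 (V) in the deletion strain, -0.11 (V) in rex-32, 0.10 (III) in rex-40, and -0.044 (IV) and -0.040 (V) in rex-23. At 1 to 5 Mb they gave 0.10 (V) in the deletion strain, 0.046 (IV) and 0.12 (V) in rex-32, 0.11 (V) in rex-40, and 0.040 (IV) and 0.098 (V) in rex-23. With 20 top partners 4 were shared. The share of peaks on X was 97.2% among peaks at or above the median score, 96.9% at scores of at least 200 and 91.25% at the ceiling. Depth is unknown for balanced contacts.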

Other observations

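Strong autosomal SDC-3 peaks stood in clusters. Of the 7 autosomal peaks at the ceiling score, 2 lay between V:3,040,587 and 3,045,442, 2 between V:7,646,759 and 7,662,840, 2 between V:9,695,229 and 9,705,000 and 1 between II:12,550,625 and 12,553,933 (WS190). Chromosomes I, III and IV had 0 peaks at the ceiling.

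The tests in this paragraph were chosen after the result was seen. The bin IV:13,500,001-13,550,000, which holds dcap-2 and rsd-2, had a mean contact of 0.474, 0.522 and 0.477 with 14 X bins between 1.55 and 3.05 Mb in the deletion, rex-32 and rex-40 strains, and 0.0608 in the rex-23 strain. The 14 X bins were not all adjacent and were chosen in the same data, so the size of this difference depends on that choice. A processing difference of the whole rex-23 library was weighed. Of 647623 pairs of a bin and a 10-bin window on another chromosome, 0 others were over 2-fold apart in that library. That limit was set after the pattern was seen and does not read smaller differences, so a processing difference stays open. A stretch of IV over 100 kb long lying on X in the other 3 strains was argued against. The neighbouring bins were at most 1.20 times as high there as in the rex-23 strain. Only neighbouring bins were read, so a shorter stretch within the bin itself was not tested and stays open. A difference of the rex-23 strain stays open as untested.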
